A study of Mus musculus with 4 samples.

How the data were processed

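RNA of bone marrow-derived dendritic cells was measured on 4 single-colour Agilent arrays, with 1 array for each of medium, LPS, LA and LPS with LA. Per the labels, femur marrow of male C57BL/6J mice was cultured in MEM with 10% FBS and 10 ng/ml GM-CSF, used on day 6 and treated for 4 h, and the RNA was purified with a High Pure kit and labelled with Cy3 by the Low Input Quick Amp method. No time was given for medium and no pH for LA. Per the file headers, the deposited intensity of each spot is the processed signal of Feature Extraction 12.0.3.1, linear, background-subtracted and not scaled between arrays, while the submitters' processing notes name version 11.5.1.1. The authors also deposited a table of intensities for 31529 spots. It equals the processed signal times 1 factor per array (6.67 for medium, 5.82 for LPS, 8.38 for LA and 9.30 for LPS with LA), which sets the mean trimmed by 2% to 2500. Its values are linear and not centred, its column medians were 1038, 873, 1164 and 1189, and its spots were well above background on all 4 arrays, a filter that 31553 spots passed. Relative to medium its scaling lay -0.24 (LPS), 0.15 (LA) and 0.18 log2 units (LPS with LA) from the scaling used here.

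Each array held 62976 spots, of which 59305 were not controls. Spots marked as outliers by the software were left out (154, 129, 134 and 146 in the order medium, LPS, LA, LPS with LA), and 0 spots were saturated. Levels were log2 of the processed signal minus the log2 of the 75th percentile of the array (179, 174, 158 and 146), and spots of a probe were averaged. Median background was 24, 24, 24 and 23. The SD between spots used 300 probes printed 10 times. Of 56605 probes, 33767 matched 1 gene symbol of a RefSeq table by transcript identifier, 0 matched several and 22838 matched none. Transcript identifiers were the only link to genes, since the array files carry no gene names. The 23462 symbols gave 23451 genes with a value, each taken from its brightest probe by the mean over the arrays, and of 775 list genes 14 had no probe. The array headers name the mm9 build and the gene names come from GRCm38.p6, and no coordinate was used.

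Differences were taken for LPS against medium, LA against medium, LPS with LA against LPS, LPS with LA against LA, and for the LA difference with LPS minus the LA difference without it. Genes well above background on both arrays (on all 4 for the last) counted as at least 2-fold apart from 1 log2 unit. For a gene well above background on 1 array only, the bound took the higher of its dim value and the lowest signal well above background on that array. Outside the share of LPS-higher genes, no bound was given in 2 cases. Either another probe of the gene was well above background on the dim array, or the gene's signal did not exceed that value. With 1 array per group no test between conditions was possible, and the lists are described against random lists only. A list used its members well above background on at least 1 array, and its median was placed among 10000 random lists matched on level in 20 bins. A list stood apart outside the central 95% of random lists and was described from 5 members. List members above background on 1 array entered the counts of higher and lower genes at their bound. Members without a bound entered as no difference and so counted as neither. The 35 lists and these choices were fixed before the data were examined, except where said otherwise. The lists described were chosen after their percentiles had been seen, so the members named from them follow that choice.

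Named genes followed a rule fixed in advance. It took (a) 12 inflammatory and maturation genes with their level on each array and (b) the 6 largest differences each way for LPS against medium, LA against medium and LPS with LA against LPS. Genes under (b) were measured genes with an ordinary symbol whose other measured probes went the same way and that stayed at least 2-fold apart under normexp, quantile normalization and median scaling. It further took (c) up to 4 largest bounds each way for the same comparisons, (d) the 2 highest and 2 lowest measured members of each list described, and (e) the 4 largest differences each way for LPS with LA against LA and for the difference of differences, under the conditions of (b). Genes outside the rule are marked where they are named. The value of 1 gene that the rule names is not reported here.

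R 4.3.3 with limma 3.58.1 was used for quantile normalization and normexp background correction (offset 50), and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 for the rest. Normexp had been planned on the mean spot signal, which the array files do not hold, and was run on the median spot signal. Other alternatives were median scaling, a 75th percentile over probes above background on all arrays, no filter on dim probes, probes above background on all arrays, the mean of all probes of a gene, the authors' table, random lists not matched on level, list members above background on both arrays, and other picks and sizes for the genes higher with LPS. Leaving out saturated spots was planned and removed nothing. Counting genes only when all their probes were at least 1.5-fold apart the same way was added after seeing the data, as was a share of LPS-higher genes restricted to those above background in medium. The calls were tested on simulated data with spot noise only over 13368 genes. At 2.5-, 4- and 8-fold, 50 of 50 genes were called, at 1.5-fold 0 of 50, and 0 of 13168 unchanged genes were called. Of 200 null lists of 20 genes 10 stood apart, and of 100 lists shifted by 0.2 log2 units 100 stood apart. The simulated errors were independent and had the spot SD of bright probes, and the simulated lists held random genes. Dim replicated probes had a median SD between spots of 0.38 to 0.49, depending on the array. These rates therefore do not carry over to dim genes or to lists whose members move together.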

Results

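Dendritic cells are antigen-presenting cells of the immune system. Those measured here were grown from the bone marrow of male C57BL/6J mice with GM-CSF, a growth factor that drives myeloid precursors towards dendritic cells. Total RNA of 4 groups was hybridised to single-colour Cy3 arrays, with 1 array per group: medium, LPS (100 ng/ml), LA (20 mM) and LPS with LA, where the treatments lasted 4 h. The labels write LA as L-(+)-LA, and the series title speaks of lactate. There were no replicates, so every difference below is a difference between 2 arrays, without a p-value or a spread between cultures, and the number of arrays limits the precision. Of 59305 spots that were not controls, 61.5% were well above background in medium, 56.5% with LPS, 64.1% with LA and 63.6% with LPS and LA. The median processed intensity was 30.2, 28.2, 27.9 and 25.4 in the same order. Probes printed 10 times on an array had a median SD between spots of 0.052, 0.053, 0.051 and 0.054 log2 units, an error that covers the spots and leaves out labelling, culture and animal. Most of these probes were bright. Those not well above background had a median SD of 0.41, 0.40, 0.49 and 0.38, so dim genes are far less precise. Levels are log2 signals relative to the 75th percentile of the array. A gene was measured in a comparison when its probe was well above background on both arrays, and a gene above background on 1 of them has only a bound, given as at least N-fold.

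Inflammatory and maturation genes chosen in advance were read on each array first. Il6, a pyrogenic cytokine, stood at -1.63 in medium, 4.68 with LPS, -2.68 with LA and -2.10 with LPS and LA. Il12a and Il12b encode the subunits of interleukin-12, which drives type 1 T cell responses. Il12a lay at -2.07, 2.19, -2.96 and -1.38 in that order, and Il12b at 0.44, 6.29, -0.57 and -0.85. Tnf, a central inflammatory cytokine, had levels of 2.15, 6.69, 0.86 and 1.46. The levels of Il1b, the inflammasome-processed interleukin, were 2.02, 6.19, 2.26 and 2.54. Cxcl10, an interferon-induced chemokine, lay at -1.34, 6.36, -3.65 and -1.59. For Nos2, the inducible nitric oxide synthase, the levels were 1.61, 4.57, 0.98 and 1.01. The costimulatory genes Cd40 and Cd86 lay at -2.25, 1.41, -3.57 and -2.97 and at 2.28, 3.70, 0.57 and 0.78. The other probes of Cd86 lay at 2.14, 2.46, 0.46 and 0.08 and at -1.02, 0.01, -1.84 and -1.73. Ccr7, the receptor that guides dendritic cells to lymph nodes, lay at 1.80, 3.50, 1.33 and 1.57. Il10, an anti-inflammatory cytokine, and Ifnb1, encoding interferon beta, were well above background on the LPS array only, at 0.36 and 3.87.

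**Figure D1:**
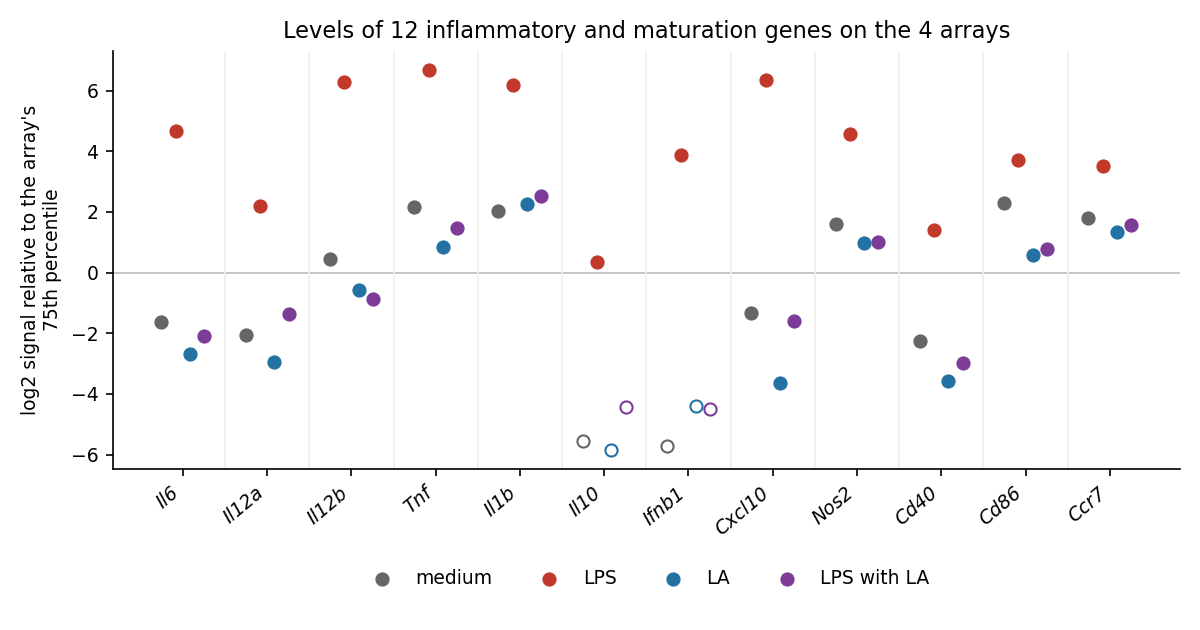
Log2 signal relative to the 75th percentile of the array (vertical axis) of 12 genes chosen in advance (horizontal axis) on the arrays of medium, LPS, LA and LPS with LA, with 1 point per array. Open points were not well above background; every gene was highest with LPS, with Il6 at 4.68 against -2.10 with LPS and LA.

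LPS, a bacterial cell wall component sensed through TLR4, was set against medium to describe the inflammatory response of these cells. Cxcl10 was 208-fold higher with LPS, and Il1a, an interleukin-1 family cytokine, was 129-fold higher. Cd69, an early activation marker of leukocytes, was 112-fold higher, Cxcl1, a neutrophil attractant, 81.0-fold, Il6 79.3-fold and Ccl4, a chemokine for monocytes and T cells, 78.4-fold. Ifnb1 was at least 231-fold and Il10 at least 20.3-fold higher. At the other end, Rab7b, a Rab GTPase of late endosomes, was 24.6-fold lower and Il6ra, the interleukin-6 receptor alpha chain, 11.1-fold lower. Ang, a secreted ribonuclease, was 9.95-fold lower, Ppcs, an enzyme of coenzyme A synthesis, 8.95-fold, Slc36a1, a lysosomal amino acid transporter, 8.91-fold and Pls1, an actin-bundling protein, 8.57-fold.

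The same comparison over the gene lists fixed in advance showed the inflammatory lists higher. Of 20 proinflammatory cytokine genes above background on at least 1 array, 14 were at least 2-fold higher, 0 lower and 6 neither, with a median log2 difference of 2.85 (quartiles 0.90 and 5.09). Il1a (7.01) and Il6 (6.31) led this list, and Csf1, a macrophage growth factor, lay at -0.21. Of 20 chemokine genes, 16 were higher and 4 neither. Their median was 3.85, or 2.93 with dim members at their bound and 1.76 with normexp, and Cxcl10 (7.70) and Cxcl1 (6.34) led. All 40 interferon-stimulated genes were at least 2-fold higher (median 2.78), among them the guanylate-binding protein gene Gbp5 (6.11) and the antiviral gene Oasl1 (5.96). In the NF-kB pathway and feedback list, 23 of 26 were higher and 3 neither (median 1.92), with the phosphatase gene Dusp2 at 5.50 and the cytokine signalling suppressor Socs3 at 5.04. Maturation genes were higher in 18 of 24 and neither in 6 (median 1.53), with the T cell costimulator Tnfsf9 at 4.73, Cd40 at 3.66, Cd48 at -0.64 and Tnfrsf9 at -0.28. MHC class I presentation genes had a median of 0.77, with 6 of 19 higher and 13 neither, and included the peptide transporter Tap1 (1.17) and the class I transactivator Nlrc5 (2.19, with its other probe at 0.63), while the peptide trimmer Erap1 lay at -0.56. These 6 lists lay at percentile 100 of random lists matched on level.

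Enzyme and sensor genes went both ways within their lists. Of 18 genes of nitric oxide, prostaglandin and itaconate synthesis, 5 were at least 2-fold higher, 1 lower and 12 neither (median 0.36, percentile 99.2, or 94.7 with normexp background correction). The prostaglandin synthase Ptgs2 (6.09) and the itaconate enzyme Acod1 (3.83) were highest, with the prostaglandin receptor Ptger2 at -1.30 and Ptgs1 at -0.82. Inflammasome genes were higher in 6 of 16, lower in 2 and neither in 8 (median 0.59, percentile 99.8). Casp4, a caspase that binds intracellular LPS, was at 2.68, and Txnip, a thioredoxin inhibitor, at -1.34. P2rx7, an ATP-gated channel, lay at -1.42, but its 3 probes ranged from -1.98 to 0.35. Among 27 pattern recognition receptors and adaptors, 9 were higher, 4 lower and 14 neither, and the list median was 0.16 (-0.09 to 0.22 between scalings, and 0.15 to 0.22 relative to all genes). Tlr3, a receptor for double-stranded RNA, was at 2.80 and Clec4e, a receptor for mycobacterial glycolipid, at 2.78, while Tlr4, the LPS receptor, was at -2.11 and the beta-glucan receptor Clec7a at -1.48.

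Lists of antioxidant, lipid and lysosomal genes were lower with LPS relative to level-matched lists. The NRF2 oxidative stress list had a median of -0.42 (percentile 0.010), with 2 of 24 members at least 2-fold higher, 3 lower and 19 neither. The glutathione transferase Gsta3 was at -1.31, the carbonyl reductase Cbr3 at -1.13 and the cystine transporter Slc7a11 at 1.54. LXR and PPAR lipid genes had a median of -0.43 (percentile 0.27), with 0 higher, 1 of 23 lower and 22 neither. The desaturase gene Scd2 lay at -2.17, the lipoprotein lipase gene Lpl at -0.93 and the fatty acid oxidation enzyme Acadl at 0.85. Lysosomal genes had a median of -0.26 (percentile 0.060, or 8.56 without matching on level), with 0 of 25 higher, 3 lower and 22 neither. Lipa, the lysosomal acid lipase, was at -1.15. Tfeb, a regulator of lysosomal genes, was at -1.22, with its 3 probes between -1.24 and 0.30.

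Of 13592 genes measured in medium and with LPS, 1107 were at least 2-fold higher and 1019 lower, and a bound put 330 further genes at least 2-fold higher and 320 lower. The largest bounds were those of Ifnb1, of the calmodulin-binding protein Pcp4 (at least 60.3-fold), of the channel gene Calhm6 (at least 45.9-fold) and of the vomeronasal receptor Vmn2r112 (at least 38.5-fold). Among genes lost from the LPS array, Prl6a1, a prolactin family member, was at least 16.1-fold lower, Slc35f2, a solute carrier, at least 10.6-fold, Fgf4, a growth factor, at least 10.2-fold and Tas2r134, a bitter taste receptor, at least 10.2-fold. Prl6a1 and Fgf4 were well above background on the medium array only. Different probes of a gene had a median SD of 0.23, and in 74.6% of the 686 genes at least 2-fold apart with several measured probes all probes were at least 1.5-fold apart the same way. The counts became 682 and 318 with normexp background correction, and the share of higher genes among those 2-fold apart, 52.1%, became 68.2%, against 41.0% when scaled over probes above background on all arrays and 30.1% in the authors' deposited values.

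LA was set against medium to describe what it does without LPS. The HIF-1 and glycolysis lists were lower with LA. Egr1 and Fos, transcription factors induced within minutes of stimulation, were 15.8-fold and 8.55-fold higher, and Atp1b1, a sodium pump subunit, 8.83-fold higher. Tmod1, an actin filament capping protein, was 21.1-fold and Zfp715, a zinc finger gene, 7.89-fold higher, both bright on the LA array alone, and Rnu3b1, a small nucleolar RNA, was 7.59-fold higher. Egln3, an oxygen-sensing prolyl hydroxylase induced by HIF-1, was 10.1-fold lower and Ankrd37, another HIF-1 target, 10.0-fold lower. Mgarp, a mitochondrial protein gene, was 11.2-fold lower, Hspa1b, an inducible heat shock protein, 10.5-fold, Cox10, a haem synthesis enzyme of mitochondria, 9.66-fold and Tas2r134 12.9-fold.

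The HIF-1 hypoxia list had the lowest median of the lists described for LA against medium, -1.57 (quartiles -2.69 and -0.94, percentile 0). Of its 21 members above background on at least 1 array, 15 were at least 2-fold lower, 0 higher and 6 neither, and Plin2, a lipid droplet protein, lay at 0.14. Glycolysis genes had a median of -0.73 (percentile 0), with 7 of 23 lower, 0 higher and 16 neither. The glycolytic enzyme Tpi1 lay at -2.28, the glucose transporter Slc2a1, which is in both lists, at -2.27 and the muscle-type phosphofructokinase Pfkm at 0.37. Unfolded protein and heat shock genes were lower in 5 of 23 and higher in 0, with 18 neither (median -0.53, percentile 0.010), led by Hspa1b (-3.39) and Hspa1a (-2.16). The integrated stress list had 3 of 22 lower and 19 neither (median -0.26, percentile 0.91), with the mTOR inhibitor Ddit4 at -3.16 and the stress factor Atf3 at -1.98. Metallothionein and zinc genes were lower in 3 of 9 and neither in 6. Their median of -0.77 lay at percentile 0.040, or 7.74 when all probes of a gene were averaged, with the zinc-binding Mt2 at -2.80. The zinc importer Slc39a10 lay at -1.72 with its brightest probe and at 0.17 as the mean of its probes. NRF2 genes had a median of -0.23 (percentile 1.44, or 4.63 with quantile normalization), with 4 of 24 lower and 20 neither, including the haem oxygenase Hmox1 (-2.07). Oxidative phosphorylation genes had a median of -0.31 (percentile 0.17) with 31 of 31 less than 2-fold apart, and included Atp5b (-0.81), Sdhd (-0.77) and Uqcrc1 (0.59). Housekeeping genes had a median of -0.28 (percentile 0.17), with 2 of 32 lower and 30 neither, among them the glycolytic gene Pgk1 (-1.53) and Snrpd3 (-1.23). The medians of the integrated stress, NRF2 and oxidative phosphorylation lists lay near this housekeeping median, as did those of MHC class II genes and macrophage markers below.

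Interferon-stimulated, NF-kB, maturation and MHC class I lists were also lower with LA, while the cytokine list did not stand apart. With normexp, however, the medians of NF-kB (-0.28) and maturation genes (-0.27) lay at that of housekeeping genes (-0.27). Those of interferon-stimulated (-0.56) and MHC class I genes (-0.42) lay below it. Interferon-stimulated genes had a median of -0.69 (quartiles -1.02 and -0.44), with 12 of 39 at least 2-fold lower, 0 higher and 27 neither. The antiviral genes Rsad2 (-2.95, with its other probe at -1.31) and Ifit2 (-2.70) were lowest, and Gbp5 lay at 0.34. NF-kB pathway genes had a median of -0.41, with 3 of 26 lower, 3 higher and 20 neither: the NF-kB inhibitors Tnip3 (-3.06) and Tnfaip3 (-2.68) were lowest, and Socs1 (1.51) and Socs3 (1.37) were highest. Maturation genes had a median of -0.48, with 5 of 22 lower, 0 higher and 17 neither, including Tnfrsf9 (-1.82) and Cd86 (-1.71). These lists lay at percentile 0, and MHC class I genes, with a median of -0.43 and 19 of 19 less than 2-fold apart, at 0.030. MHC class II genes had a median of -0.29 (percentile 2.06), with 2 of 15 lower and 13 neither, including H2-Aa (-1.16). Chemokine genes split, with 2 of 18 higher, 2 lower and 14 neither (median -0.37, percentile 0.23, or 3.29 with normexp). Ccl2, a monocyte attractant, was at 2.88 and Ccl3 at 0.85, while Cxcl10 was at -2.31 and Cxcl16 at -0.95. Cytokine genes had a median of -0.02 (percentile 29.4; -0.08 to 0.16 between scalings, and -0.10 to -0.01 relative to all genes), with 2 of 20 higher, 5 lower and 13 neither. The highest member was Osm at 1.84. Of the cytokines chosen in advance, Tnf was at -1.29, Il6 at -1.06, Il12b at -1.01, Il12a at -0.89 and Il1b at 0.24, and Cd40 was at -1.32.

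Markers of some other cells that such cultures can hold differed with LA. Neutrophil and myeloid precursor markers had a median of 0.60 (quartiles 0.35 and 0.78, percentile 100), with 1 of 22 at least 2-fold higher and 21 neither. The chemokine receptor Cxcr2 (1.18) and the granulocyte factor Cebpe (0.90) were highest, and the growth factor receptor Csf3r lay at -0.05. Mast cell, basophil and eosinophil markers had a median of 0.63 (percentile 100), with 4 of 17 higher and 13 neither, including the eosinophil peroxidase Epx (1.74) and the mast cell tryptase Tpsb2 (1.25). Macrophage and monocyte markers had a median of -0.30 (percentile 0.23), with 1 of 25 higher, 2 lower and 22 neither. The fractalkine receptor Cx3cr1 was at -1.58, the complement gene C1qa at -1.15 and the efferocytosis receptor Mertk at 1.03. Dendritic cell markers, at a median of 0.12 (percentile 82.1) with 1 of 18 higher and 17 neither, did not stand apart. Nor did erythroid markers (median 0.29, percentile 90.45) or lymphocyte and NK markers (median 0.12, percentile 65.7). Fibroblast, stromal and endothelial markers had a median of -0.35 (percentile 1.44), with 2 of 12 lower and 10 neither, such as Sparc (-1.33), but lay at percentile 19.3 over probes above background on all arrays. Between scalings their median lay at -0.44 to 0.03, and at -0.49 to -0.10 relative to all genes.

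Of 14555 genes measured in medium and with LA, 454 were at least 2-fold higher and 484 lower, with 284 and 255 further genes by their bound. Olfr655, an olfactory receptor (at least 16.1-fold), P2ry12, an ADP receptor (at least 12.2-fold), and Gcnt4, a glycosyltransferase (at least 8.45-fold), were above background on the LA array only, and Tifab, a relative of the signalling adaptor Tifa, was at least 15.9-fold higher. Lower by their bound were Pls1 (at least 31.9-fold), Prl6a1 (at least 22.2-fold), Fgf4 (at least 16.2-fold) and Apcdd1, a Wnt inhibitor (at least 15.4-fold). Probes of a gene had a median SD of 0.24, and all probes were at least 1.5-fold apart the same way in 48.1% of 235 genes at least 2-fold apart. The counts became 73 and 164 with normexp, and the share of higher genes among those 2-fold apart, 48.4%, became 30.8%, against 65.7% in the authors' deposited values.

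**Figure D2:**
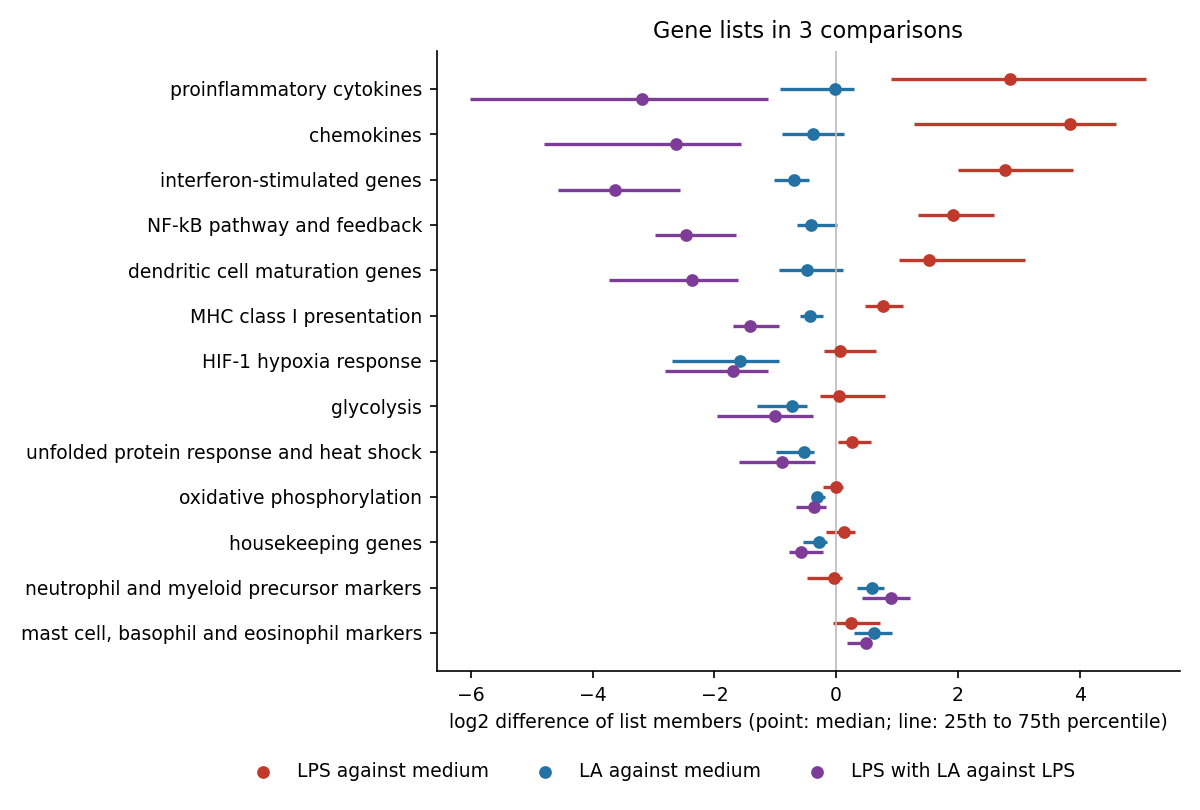
Median log2 difference (points) and 25th to 75th percentile (lines) of list members above background on at least 1 array, for 13 gene lists (vertical axis) in LPS against medium, LA against medium and LPS with LA against LPS. Interferon-stimulated genes lie at 2.78, -0.69 and -3.64, HIF-1 genes at 0.07 (-0.16 to 0.13 between scalings, 0.07 to 0.11 relative to all genes), -1.57 and -1.70; dim members are drawn at their measured value.

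LPS with LA was set against LPS to ask whether lactate attenuates the inflammatory response, as the series title words it. The genes highest with LPS were far lower on the array of LPS with LA. A failed LPS stimulation in that culture cannot be told apart from an effect of LA. Cxcl10 was 247-fold lower, the interferon-induced genes Ifit2 and Ifit3 165-fold and 128-fold, Il12b 142-fold, Cd69 115-fold and Il6 110-fold. Ifnb1 was at least 250-fold lower, the TNF family cytokine Tnfsf15 at least 198-fold, Il1a at least 196-fold, Cxcl1 at least 132-fold and Il10 at least 21.9-fold. Egr1 was 18.6-fold and Fos 13.7-fold higher, as were genes low with LPS: Il6ra was 18.1-fold and Rab7b 17.2-fold higher. Lpar5, a lysophosphatidic acid receptor, was 13.5-fold and Tmem150b, a membrane protein gene, 12.7-fold higher.

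The lists higher with LPS were lower with LPS and LA than with LPS. All 40 interferon-stimulated genes were at least 2-fold lower, with a median of -3.64 (quartiles -4.56 and -2.57). Of 19 cytokine genes, 14 were lower, 1 higher and 4 neither, with a median of -3.19, or -3.09 with dim members at their bound. Among members above background on both arrays, Il12b (-7.15) and Il6 (-6.78) were lowest, while Il1a and Tnfsf15 were lower still by their bound. Tnf lay at -5.23, Il1b at -3.65 and Il12a at -3.57, while the interleukin-17 receptor gene Il17ra was at 1.04 and Osm at 0.88. Chemokine genes were lower in 17 of 20 and neither in 3 (median -2.63, or -2.47 with bounds and -1.95 with normexp). Ccl4 lay at -5.94 and the stromal chemokine Cxcl12 at 0.26. NF-kB genes were lower in 21 of 26 and neither in 5 (median -2.46), with Tnfaip3 at -5.80 and Dusp2 at -5.60. Maturation genes were lower in 19 of 24 and neither in 5 (median -2.37, or -1.62 with normexp). Tnfsf9 lay at -5.29, Cd40 at -4.39, Cd86 at -2.92 and Ccr7 at -1.93, with Cd48 at 0.95. MHC class I genes were lower in 14 of 19 and neither in 5 (median -1.41), with the transactivator Nlrc5 at -2.20 (its other probe at -0.80) and the immunoproteasome subunit Psmb9 at -2.14. These 6 lists lay at percentile 0. MHC class II genes were lower in 6 of 15 and neither in 9 (median -0.79, percentile 0.91, or 3.24 with the mean of all probes). H2-Ob lay at -2.15 and H2-Eb2 at -1.84, with its other probe at -0.14. Nos2 was at -3.56.

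Several lists lower with LA alone were lower in this pair as well. HIF-1 genes had a median of -1.70 (quartiles -2.81 and -1.12, percentile 0), with 16 of 21 at least 2-fold lower, 0 higher and 5 neither. The lipid droplet protein Hilpda lay at -3.76, Egln3 at -3.03 and the mitophagy receptor Bnip3l at 0.10. Glycolysis genes were lower in 12 of 23, higher in 1 and neither in 10 (median -1.002, percentile 0.010), with the platelet phosphofructokinase Pfkp at -3.11, Slc2a1 at -2.91 and the regulatory enzyme Pfkfb4 at 1.47. Unfolded protein and heat shock genes were lower in 10 of 23 and neither in 13 (median -0.89, percentile 0.030), with Hspa1b at -5.75 and Hspa1a at -5.33. Metallothionein and zinc genes were lower in 5 of 9, higher in 1 and neither in 3 (median -1.36, percentile 0.010), with Mt2 at -3.70, the zinc transporter Slc30a4 at -2.76 and Slc39a10 at 1.28. Housekeeping genes had a median of -0.57 (percentile 0.48), with 4 of 32 lower and 28 neither, among them Pgk1 (-1.91) and Ywhaz (-1.12). Integrated stress genes did not stand apart here (percentile 17.4, or 0.915 with the mean of probes), with 7 of 23 lower and 16 neither, such as the stress gene Nupr1 (-5.23). Nor did oxidative phosphorylation genes (percentile 9.07, or 0.47 without matching on level; 2 of 31 lower and 29 neither) or stromal markers (percentile 38.2; 2 of 13 lower and 11 neither). Relative to all genes the medians of these lists lay at -0.27 to -0.04, -0.46 to -0.15 and -0.46 to -0.06 between scalings, while the medians themselves took both signs.

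**Figure D3:**
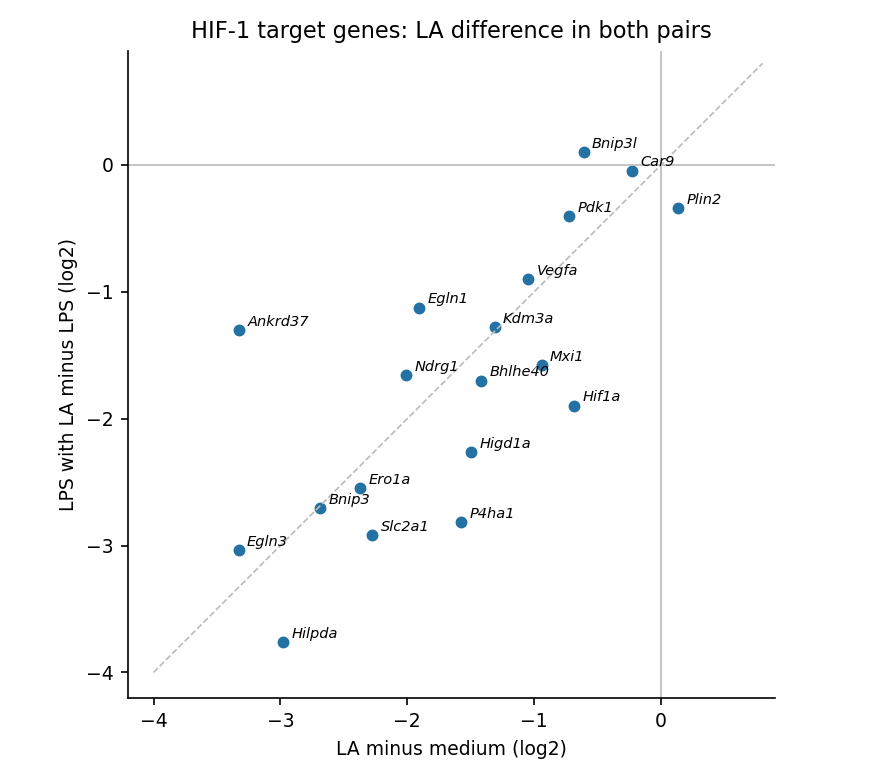
LA minus medium (horizontal axis, log2) against LPS with LA minus LPS (vertical axis, log2) for 19 HIF-1 target genes well above background on all arrays, 1 point per gene, with equality dashed. Of these, 17 lie below 0 in both pairs, which share no array.

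Further lists stood apart, some on the lower and some on the higher side. The medians of the inflammasome, nitric oxide and apoptosis lists lay near the housekeeping median of -0.57 (percentile 0.48) in this pair. Inflammasome genes had a median of -0.70 (percentile 0.84), with 2 of 16 at least 2-fold higher, 7 lower and 7 neither, including Casp4 (-3.05). Genes of nitric oxide, prostaglandin and itaconate synthesis had a median of -0.48 (percentile 1.49, or 4.85 with quantile normalization), with 3 of 18 higher, 7 lower and 8 neither, including Ptgs2 (-5.95) and Ptgs1 (1.41). Apoptosis and p53 target genes had a median of -0.57 (percentile 0.36), with 5 of 24 higher, 8 lower and 11 neither, including Plk2 (-4.08) and the proapoptotic Bid (1.38). NRF2 genes, lower with LA alone, were not lower here and had a median of 0.16 (percentile 98.4, or 68.0 without matching on level), with 1 of 24 at least 2-fold higher, 5 lower and 18 neither. The oxidative stress gene Osgin1 lay at 1.44, Slc7a11 at -2.52 and the autophagy adaptor Sqstm1 at -2.26. Lysosomal genes had a median of 0.27 (percentile 99.5, or 85.1 without matching), with 3 of 26 higher, 1 lower and 22 neither, including the cholesterol transporter Npc1 (1.24) and the membrane protein Lamp2 (-1.07). Neutrophil markers had a median of 0.90 (quartiles 0.42 and 1.22, percentile 100), with 10 of 22 higher and 12 neither. Cxcr2 was at 3.41, the gelatinase Mmp9 at 2.72 and the iron-binding Lcn2 at -0.30. Mast cell, basophil and eosinophil markers had a median of 0.49 (0.38 with bounds, percentile 99.1, or 96.5 without matching), with 0 of 18 higher, 1 lower and 17 neither. The eosinophil ribonuclease Ear1 lay at 0.94 and the histamine-forming enzyme Hdc at -2.99. Neither macrophage and monocyte markers (median -0.43, percentile 3.62, 2 of 25 higher, 6 lower and 17 neither) nor dendritic cell markers (median 0.02, percentile 58.4, 3 of 18 higher, 5 lower and 10 neither) stood apart. Relative to all genes their medians lay at -0.50 to -0.13 and at -0.08 to 0.19 between scalings, while the medians themselves took both signs. The scavenger receptor Marco was at -4.21 and the monocyte receptor Ccr2 at 2.64.

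Of 437 genes at least 4-fold higher with LPS than in medium, 314 were above background in medium and 123 were not, so that their difference is a bound. Among the 437, 436 were at least 1.5-fold lower with LPS and LA than with LPS, a share of 99.8% (95% Wilson interval 98.7 to 100.0%, across genes, which are not replicates), and 0 were higher. Their median difference, with dim genes at their bound, was -2.93 (quartiles -3.75 and -2.32). Over the 314 genes alone the share was 100% and the median -3.10, a selection added after seeing the data. Genes of the same LPS level were lower in 29.7% and higher in 16.5%. These genes were picked on the LPS array, which is also in this pair, and picking on the array of LPS with LA instead gave 66 genes, of which 4.55% were lower. Set against medium, the 437 genes stood at a median of 2.88 with LPS, -0.16 with LA and -0.18 with LPS and LA, with dim genes at their measured value. The 314 genes stood at 2.66, -0.40 and -0.38. Over the 76 measured genes at least 4-fold lower with LPS, the median of LPS with LA minus LPS was 2.23. They were picked as low on the LPS array, which is also in this pair, so part of this rise follows from the pick.

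Of 13631 genes measured with LPS and with LPS and LA, 1567 were at least 2-fold higher and 1698 lower when LA was present, with 361 and 373 further genes by their bound. Higher by their bound were Gna12, a G protein subunit (at least 15.3-fold), Tmem86a, a lysoplasmalogenase family gene (at least 14.5-fold), Sppl2b, an intramembrane protease (at least 12.7-fold), and Kank4, an adaptor of the cytoskeleton (at least 18.5-fold), above background on the array of LPS with LA only. Probes of a gene had a median SD of 0.31, and all probes were at least 1.5-fold apart the same way in 74.1% of 1129 genes at least 2-fold apart. The counts became 634 and 1102 with normexp and 3043 and 923 in the authors' deposited values, and the share of higher genes, 48.0%, became 36.5% and 76.7%, against 61.0% when scaled over probes above background on all arrays.

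LPS with LA was set against LA to describe the LPS difference in the presence of LA. Whether the LPS given with LA was effective is not known. Few of the genes that LPS alone set apart were apart here. Cxcl10 was 4.19-fold higher, Il12a 2.99-fold, while with their brightest probe Tnf (0.60), Il6 (0.58), Nos2 (0.03) and Il12b (-0.28) lay less than 2-fold apart. The other probe of Tnf lay at 1.13. Tlr3 was at 2.37, and the interferon-stimulated genes Rsad2 and Isg20 at 1.27 and 1.03, with their other probes at 0.03 and -0.67. Of the 437 genes at least 4-fold higher with LPS than in medium, 15 were still at least 2-fold higher than with LA, and the median of all 437 was 0.01, or 0.08 over the 314 above background in medium. With normexp 1 of these 15, Rsad2 (1.09), stayed at least 2-fold higher, and Cxcl10 (0.72), Tlr3 (0.66) and Il12a (0.65) did not. Over the 76 genes at least 4-fold lower with LPS, the median was 0.03.

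The inflammatory lists lay close to 0 in this pair. Interferon-stimulated genes had a median of 0.05 (percentile 88.6), with 2 of 39 at least 2-fold higher and 37 neither. Chemokine genes had a median of 0.10 (percentile 95.6), with 2 of 17 higher and 15 neither, and the eosinophil attractant Ccl24 lay at -0.80. Cytokine genes had a median of -0.02 (percentile 52.5), with 1 of 17 higher, 1 lower and 15 neither, and this median lay at -0.02 to 0.10 between scalings, and at 0.002 to 0.088 relative to all genes. NF-kB genes had a median of 0.16 (percentile 100.0) with 26 of 26 less than 2-fold apart, including Dusp2 (0.62), Dusp5 (0.62) and Nfkb2 (-0.44). Pattern recognition genes had a median of 0.06 (percentile 93.5) with 1 of 27 higher and 26 neither, and the adaptor gene Myd88 lay at 0.67. MHC class II genes had a median of -0.19 (percentile 0.12, or 3.89 without matching on level), with 1 of 15 lower and 14 neither, and H2-Eb2 lay at -1.69, with its other probe at 0.49. MHC class I genes had a median of -0.16 (percentile 0.26, or 4.22 without matching), with 19 of 19 less than 2-fold apart. Oxidative phosphorylation genes had a median of -0.16 (percentile 0.010) with 31 of 31 less than 2-fold apart. Neutrophil markers had a median of 0.21 (percentile 100) with 22 of 22 less than 2-fold apart, led by Itgb2l (0.42) and Retnlg (0.38). Fibroblast, stromal and endothelial markers had a median of 0.34 (percentile 99.3, or 96.3 over probes above background on all arrays), with 2 of 13 higher, 1 lower and 10 neither, including the collagen gene Col1a1 (1.08).

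Of 14905 genes measured with LA and with LPS and LA, 135 were at least 2-fold higher and 223 lower, with 164 and 234 further genes by their bound. Among genes that stayed at least 2-fold apart under normexp, quantile normalization and median scaling, the vomeronasal receptor Vmn2r12 was 7.90-fold higher, the nuclear import factor Tnpo2 6.22-fold, the DNA repair gene Ercc8 4.22-fold and the Integrator subunit Ints5 2.64-fold. Tmod1 was 23.7-fold lower, Zfp715 lay at -3.52, and Endod1, a nuclease domain gene, was 7.01-fold and Rcc1l, a mitochondrial ribosome factor, 5.63-fold lower. The other probes of Tnpo2 (0.06), Ercc8 (0.06), Endod1 (-0.33) and Rcc1l (-0.36) lay near 0. Probes of a gene had a median SD of 0.20, and all probes were at least 1.5-fold apart the same way in 14.9% of 74 genes at least 2-fold apart, while normexp left 8 genes higher and 23 lower, so that the share of higher genes, 37.7%, became 25.8%.

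**Figure D4:**
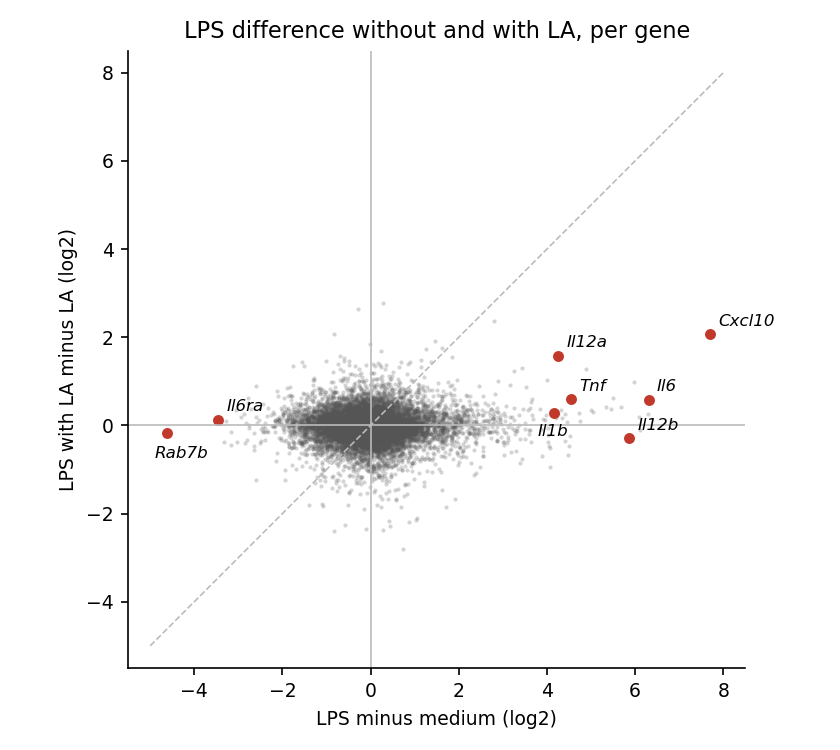
LPS minus medium (horizontal axis, log2) against LPS with LA minus LA (vertical axis, log2) for 13368 genes well above background on all arrays, 1 point per gene, with 8 genes named and equality dashed. The cloud lies along the horizontal axis, with Cxcl10 at 7.70 and 2.07 and Il6 at 6.31 and 0.58.

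The LA difference with LPS minus the LA difference without LPS equals the LPS difference with LA minus the LPS difference without LA. As the LPS difference with LA was small, the values below largely repeat LPS against medium with the sign turned. They would do so too if the LPS given with LA had been ineffective. The difference of differences was lowest for Cd69 (-6.72), Gbp5 (-6.22), Il12b (-6.14) and Ccl4 (-6.03). It was highest for Rab7b (4.44), Il6ra (3.60, with its other probe at 1.86), the glycogen phosphatase gene Epm2a (3.50) and the lipase gene Daglb (3.41). Il6 lay at -5.73, Cxcl10 at -5.63, Tnf at -3.94, Il1b at -3.89, Cd40 at -3.07, Nos2 at -2.93 and Il12a at -2.68. Interferon-stimulated genes had a median of -2.68, with 37 of 38 at least 2-fold lower and 1 neither. Chemokine genes (11 of 14 lower, 3 neither) and cytokine genes (9 of 14 lower, 5 neither) both had a median of -2.46. NF-kB genes had a median of -1.95 (23 of 26 lower, 3 neither), maturation genes of -1.47 (15 of 21 lower, 6 neither) and MHC class I genes of -0.98 (9 of 19 lower, 10 neither). Each of these lists lay at percentile 0.

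HIF-1 genes did not stand apart in this difference (median -0.02, percentile 53.02, 1 of 19 higher, 2 lower and 16 neither), and their median lay at -0.07 to 0.25 between scalings, and at -0.06 to 0.01 relative to all genes. Ankrd37 was at 2.02 and the collagen hydroxylase P4ha1 at -1.24. NRF2 genes had a median of 0.42 (percentile 100.0, 4 of 24 higher, 2 lower and 18 neither), with Gsta3 at 1.35 and Slc7a11 at -1.54. Lysosomal genes had a median of 0.28 (percentile 99.8, or 96.1 without matching on level, 2 of 25 higher and 23 neither), with Npc1 at 1.14. Neutrophil markers had a median of 0.31 (percentile 99.9, or 96.9 without matching, 4 of 22 higher and 18 neither), with Cxcr2 at 2.23 and Mmp9 at 1.86. Of 13368 genes well above background on all arrays, 1199 were at least 2-fold higher and 1297 lower in this difference, and 66.5% of 765 such genes with several probes had all probes at least 1.5-fold apart the same way. With normexp the counts were 418 and 722, and the share of higher genes, 48.0%, was 36.7%, against 60.4% when scaled over probes above background on all arrays and 70.4% in the authors' deposited values.

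Pairs that share no array were set against each other across the 13368 genes, which are not independent replicates. The LA difference without LPS and the LA difference with LPS had a Pearson r of 0.50 and a Spearman rho of 0.47, and the SD across genes was 1.90 times as large with LPS. Without the filter on dim probes r was 0.26. Of 333 genes at least 2-fold higher with LA without LPS and 1561 with LPS, 132 were in both, where independent lists would share 38.9. Of 428 and 1625 lower genes, 265 were in both, against 52.0 for independent lists. The LPS difference without LA and the LPS difference with LA had an r of 0.02 and a rho of -0.01, and the SD across genes with LA was 0.42 of that without.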

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

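The tests of a level-dependent trend for the genes higher with LPS, of carried-over RNA and of the share of the main cell type were chosen only after the results were seen. The trend tests of the HIF-1 and neutrophil lists and the test of ineffective LPS were chosen before, with the main percentiles of those lists already seen.

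Some genes at least 2-fold apart in both pairs, and 1 list that stood apart in both, lay in opposite directions with LA without and with LPS. Medians of other lists that changed sign did not stand apart in both pairs. These differences were not tested. Ccl2 lay at 2.88 without LPS (LA minus medium) and at -1.38 with LPS (LPS with LA minus LPS). Socs1 lay at 1.51 and -3.14, and Socs3 at 1.37 and -3.35. Ang lay at -1.58 and 1.36, and the pattern recognition gene Nod1 at 1.07 and -1.12. Endod1 lay at 2.31 and -1.24. The peptidase gene Dpp4 lay at 1.22 and -1.36, with -0.13 without LPS as the mean of its probes. Slc39a10 lay at -1.72 and 1.28, with 0.17 without LPS as the mean of its probes. The NRF2 list had medians of -0.23 and 0.16, the latter with 5 of 24 members at least 2-fold lower and 1 higher. Its percentile without LPS, 1.44, became 4.63 with quantile normalization. With LPS its percentile, 98.4, became 68.0 without matching on level, so neither side held under all alternatives. Outside the genes with a name, 360 of 12912 probes above background in LPS or medium were at least 4-fold higher with LPS, and 353 of them (98.1%) were at least 1.5-fold lower with LPS and LA than with LPS.

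Genes higher with LPS lay near their unstimulated level when LA was present. A trend with signal level between arrays is argued against by genes of the same LPS level. Of those, 29.7% were at least 1.5-fold lower, against 99.8% of the genes higher with LPS. Quantile normalization left the median of the latter at -3.19 relative to all genes. That test adds little, since it could hardly have removed a fall of this size. With normexp, which corrects background and does not remove such a trend, the median was -1.94. The genes higher with LPS were picked on the LPS array, which is in this pair, so part of their fall follows from the pick. RNA of the LPS culture carried into the other sample stays open for the genes still higher than with LA: the largest share that every LPS-higher gene allows, 0.400%, limited by Ifnb1, lifts 1 of 15 such genes 2-fold, Cxcl10, but with normexp 14 of the 15 lay under 2-fold, too near background to decide, and 5 were dim with LA. A culture that received no effective LPS cannot be told apart from an effect of LA: the median of the 346 genes above background with LA or with LPS and LA, 0.07, lay at percentile 100, past the bound set in advance for excluding it, but 9 of 34 lists stood apart between these arrays and 1 culture per group makes that bound too loose, a judgement made after the value was seen. An effect of LA on the LPS response may therefore account for the pattern, as may a failed stimulation, and acidity and lactate were not separable.

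HIF-1 target genes were lower with LA in both pairs of arrays. A trend with signal level is argued against by the matching on level, under which the list lay at percentile 0 in both pairs. Quantile normalization left it at percentile 0 in both, with medians of -1.53 and -1.53. That test adds little, since the percentiles were already matched on level. The pairs share no array, and no test of a single odd array was made apart from the pattern itself. An effect of LA on hypoxia-inducible genes may account for this as a hypothesis, found and examined on the same arrays. Oxygen, cell density and acidity were not measured and stay open.

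Neutrophil markers were higher with LA in both pairs, and all 22 listed genes were above background in medium, with 0 in another list. A trend with signal level is argued against by the matching on level, under which the list lay at percentile 100 in both pairs. The test with quantile normalization repeats this, with percentile 100 in both pairs and medians of 0.69 and 1.29. It could hardly have come out otherwise. A lower share of the main cell type is not settled. Of 4 other minority lists, 3 (erythroid, lymphocyte and NK, and stromal) lay below the neutrophil list in both pairs. The differences were -0.31, -0.47 and -0.95 without LPS and -1.05, -0.68 and -0.89 with LPS. Bootstrap intervals across genes, which are not replicates, ended at -0.02 for erythroid markers without LPS and for lymphocyte and NK markers with LPS. The mast cell list differed by 0.03 and -0.41, so that without LPS it rose as the neutrophil list did. A lower share of the main cell type, a larger share of neutrophils and precursors, or an effect of LA on their transcripts may account for the pattern. No value here separates these.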

How the results depend on the processing

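Only the count of genes whose probes all went the same way and the share over genes above background in medium were chosen after seeing the data, and the other tests here were planned. No paired analysis was possible because each group holds 1 array, and no array could be left out. All arrays came from 1 slide and 1 scan, so no slide term applied. No spot was saturated, so leaving such spots out gives no values. Signal over background limits the dim genes: a gene below it on 1 array has only a bound, and differences among dim probes shrink under normexp, whose offset is added to every signal. Where not said otherwise, the cause was not tested. Of the values of single genes under the alternatives, 2930 kept direction and side of 2-fold, 95 fell below it, 57 passed it and 2 reversed. Of the list percentiles, 800 kept their side, 34 lost it and 6 gained it.

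With normexp, genes at least 2-fold apart numbered 1000 (682 higher, 318 lower) for LPS against medium, 237 (73, 164) for LA against medium, 1736 (634, 1102) for LPS with LA against LPS, 31 (8, 23) for LPS with LA against LA and 1140 (418, 722) for the difference of differences, where the main totals were 2126, 938, 3265, 358 and 2496. Without the filter on dim probes they were, in that order, 4406 (2111, 2295), 3284 (1861, 1423), 5716 (2984, 2732), 2354 (985, 1369) and 6174 (2813, 3361), which follows from the dim probes counted. Over probes above background on all arrays, LPS with LA against LA gave 220 (87, 133). In the authors' table, 1716 genes were lower for LPS against medium and 298 for LA against medium. There, 3043 were higher and 923 lower for LPS with LA against LPS, and 2017 higher and 847 lower for the difference of differences. LPS with LA against LA gave 217 there, with 120 lower. That table shifts the median of all genes by -0.24, 0.15, 0.43, 0.03 and 0.27 in the same order, and the 75th percentile over probes above background on all arrays shifts LPS against medium by -0.12, LPS with LA against LPS by 0.17 and the difference of differences by 0.14. Median scaling shifts LPS with LA against LPS by -0.11, and leaving out the filter shifts LPS against medium by 0.13, LPS with LA against LPS by -0.13 and the difference of differences by -0.13.

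The share of LPS-higher genes lower with LA was 100% with normexp, quantile normalization, median scaling, probes above background on all arrays the mean of probes and genes above background in medium, 94.1% without the filter, 98.2% in the authors' table, 97.9% when called at 2-fold, 92.2% for genes picked at 2-fold, 87.2% picked on either LPS array and 4.55% picked on LPS with LA, where the pick favours genes high there. The correlation of the LA differences was 0.26 without the filter.

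List percentiles that crossed their threshold were the following. With normexp, nitric oxide genes lay at 94.7 for LPS against medium, and for LA against medium chemokines at 3.29, pattern recognition genes at 15.4 and stromal markers at 5.15. With quantile normalization, NRF2 genes lay at 4.63 for LA against medium, and lysosomal genes at 97.4 and nitric oxide genes at 4.85 for LPS with LA against LPS. Without the filter, lactate handling lay at 9.43, NRF2 genes at 2.70 and stromal markers at 5.55 for LA against medium, and stromal markers at 96.3 for LPS with LA against LA. Over probes above background on all arrays, chemokines lay at 2.55, pattern recognition genes at 6.66 and stromal markers at 19.3 for LA against medium, and stromal markers at 96.3 for LPS with LA against LA. With the mean of probes, metallothionein lay at 7.74, lactate handling at 8.04, NRF2 genes at 2.95 and cAMP genes at 0.74 for LA against medium, MHC class II at 3.24 and integrated stress genes at 0.915 for LPS with LA against LPS and pattern recognition genes at 99.4 for LPS with LA against LA, while Dpp4 (-0.13) and Slc39a10 (0.17) reversed for LA against medium. In the authors' table, chemokines lay at 2.69, pattern recognition genes at 7.09 and stromal markers at 18.7 for LA against medium, and stromal markers at 96.4 for LPS with LA against LA. Against random lists not matched on level, lysosomal genes lay at 8.56 for LPS against medium and at 85.1 for LPS with LA against LPS, where NRF2 genes lay at 68.0, mast cell markers at 96.5, cAMP genes at 1.35, oxidative phosphorylation genes at 0.47 and macrophage markers at 0.475. MHC class II lay at 3.89 and MHC class I at 4.22 for LPS with LA against LA, and lysosomal genes at 96.1 and neutrophil markers at 96.9 for the difference of differences. Over members above background on both arrays, pattern recognition genes lay at 6.57 and stromal markers at 8.78 for LA against medium, and stromal markers at 97.1 for LPS with LA against LA.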

Other observations

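The lists below were fixed in advance and described after their percentiles had been seen, and no tests were chosen for them. Housekeeping genes had medians of -0.28 with LA against medium and -0.57 with LPS and LA against LPS, near several of the medians given here. Lactate and monocarboxylate handling genes had a median of -0.26 with LA against medium (percentile 1.54, or 8.04 with the mean of probes), with 1 of 18 at least 2-fold lower and 17 neither. The lactate exporter Slc16a3 lay at -1.38 and its chaperone Bsg at -0.97, while the sodium-coupled carriers Slc5a12 and Slc5a8 lay at 0.65 and 0.60. With LPS and LA against LPS the median was -0.52 (percentile 0.995), with 2 of 17 higher, 6 lower and 9 neither. The butyrate and niacin receptor Hcar2 lay at -2.11 and Bsg at -1.81, and the pyruvate dehydrogenase kinase Pdk2 at 2.08. Acid and pH handling genes did not stand apart in either pair, with medians of -0.07 and -0.12 that took both signs between scalings, and lay at -0.17 to -0.08 and -0.23 to -0.13 relative to all genes. The carbonic anhydrase Car13 lay at -3.19 with LPS and LA against LPS.

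The cAMP and CREB genes split, with medians of -0.09 and -0.33 that took both signs between scalings, and lay at -0.16 to 0.07 and -0.40 to -0.22 relative to all genes. With LA against medium 3 of 26 were higher, 4 lower and 19 neither: Egr1 (3.98) and Fos (8.55-fold higher) against the cAMP-responsive repressor Crem (-1.73) and Nfil3 (-1.59). With LPS and LA against LPS 8 of 27 were higher, 10 lower and 9 neither, with Egr1 at 4.22, Fos at 3.77 and the nuclear receptor Nr4a1 at -2.13. Pattern recognition genes with LPS and LA against LPS had a median of -0.53 (percentile 0.24), with 3 of 27 higher, 8 lower and 16 neither. Clec4e lay at -4.55 and Tlr1 at -3.04, while Tlr4 lay at 2.14 and the kinase gene Irak4 at 1.80. Tlr4, the LPS receptor, had levels of 1.48 in medium, -0.63 with LPS, 1.45 with LA and 1.51 with LPS and LA. With LA against medium that list had a median of -0.22 (percentile 1.27, or 15.4 with normexp) that lay at -0.28 to 0.01 between scalings and at -0.31 to -0.10 relative to all genes, with 1 of 27 higher, 3 lower and 23 neither, and Ticam2, an adaptor of Tlr4, lay at -1.37. Among dendritic cell markers, the plasmacytoid gene Tcf4 lay at -3.22 and Cd209a at 1.07 with LPS and LA against LPS.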
